A study of Bifidobacterium breve UCC2003 with 4 samples.

How the data were processed

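Total RNA of Bifidobacterium breve UCC2003, an anaerobic gut bacterium, was measured on 4 two-colour Agilent arrays, 2 for cells grown on cellobiose against glucose and 2 for cells grown on cellodextrins against glucose. Cellobiose is a disaccharide of glucose, and cellodextrins are longer chains of the same units. Per the labels, the strain was grown without oxygen in a modified MRS broth with 0.05% cysteine to an OD600 of 0.5, with 1% cellobiose, 0.85% cellodextrins or 1% glucose as the carbon source. The cellodextrin dose was therefore not the cellobiose dose. The series text states that the cellodextrin preparation held leftover glucose and that cells were collected once they were using the sugar under study. It also states that the data came from 2 independent biological replicates. The labels do not say which culture was on which array, so each array was taken as 1 replicate. If the arrays of a pair carried the same RNA, the p-values below measure technical spread alone. The labels also do not say whether the glucose RNA was shared between the comparisons. Replicate 1 of each comparison had glucose RNA in Cy3 and the other sugar in Cy5, and replicate 2 had the dyes swapped, per the labels. The 4 arrays were on 4 slides scanned on 4 days, so a slide or scan batch could not be told apart from a single array.

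Each scanner file held 10807 spots, of which 79 were negative and 465 positive controls. Per the file headers and the labels, the authors made these files with Feature Extraction 9.5. The intensity columns used here were the mean pixel brightness of each spot and the median of its local background, deposited before any correction. The same files carried a deposited log10 ratio of Cy5 over Cy3 after background subtraction and lowess dye normalization by the scanner software, per the file headers. The deposited value table of the series held the same log10 ratios by spot number, within 0.00498 after turning, with the sign of both swapped arrays turned. Its column medians were 0, 0.0423, 0 and 0.00681 in the order cellobiose replicates 1 and 2, then cellodextrins replicates 1 and 2. Its scale and direction were thereby settled, and no centring beyond that of the scanner software was found. The file of cellodextrins replicate 1 had its values rounded to 3 significant digits.

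The array carried 1888 features with 3 probes each, 5664 probes in all, of which 4599 were spotted 2 times and 1065 once. They comprised 1843 locus tags, 20 tRNA features, 7 spike-in features and 18 others (16S rRNA, plasmid, insertion sequence and unnamed coding probes). The files pair no locus tag with a gene name or product. A RefSeq table of 2016 genes was given for another strain of the species, and 0 of the locus tags matched it. Genes are therefore named by locus tag, and no function is given for a tag.

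Background was corrected here with normexp and an offset of 50, and log2 ratios were normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as outliers by the scanner software were left out, and saturated spots were kept. Spots of a probe and then the 3 probes of a feature were averaged. A probe was kept if it was well above background in at least 1 channel on both arrays of at least 1 comparison, which kept 5575 of 5643 probes and 1865 of 1881 features other than spike-ins. The typical spread between probes of a feature was 0.07 to 0.28 on the log2 scale. Ratios were turned to read as the sugar over glucose. Swapped arrays entered with sign -1, so a dye effect on a gene cancels in the mean of a pair.

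All 4 arrays were fitted together with lmFit and eBayes, with 2 residual degrees of freedom and 5.39 prior degrees of freedom. The 3 comparisons were cellobiose against glucose, cellodextrins against glucose, and the difference between both responses, which is an indirect comparison through glucose. Tests were two-sided with Benjamini-Hochberg adjustment over 1865 features, and a feature was called at an adjusted p under 0.05. Errors given with fitted log2 ratios are standard errors from this fit. The number of arrays limits the precision: the median half-width of the 95% interval was 0.52 for each sugar and 0.73 for the difference, on the log2 scale. The procedure was tested on simulated data with 1865 genes, 200 of them changed, in 20 draws. It called 47.6% of genes changed by 1 on the log2 scale and 97.6% of those changed by 2 in the cellobiose comparison. In the cellodextrins comparison these shares were 48% and 97.6%, and false calls were 5.38% and 4.8% of the calls. Simulated errors were independent between genes, with variances drawn from the spread model fitted to the arrays. They held no dye effect, no trend along the tags and no unequal spread of arrays. These shares therefore check the procedure and do not measure false calls on the real arrays.

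A window of tags and the rules for the other named features were fixed before the data were examined. Those rules picked the other features by the fitted values of these same arrays. The window held 7 neighbouring tags, Bbr_0104 to Bbr_0110, where general knowledge of the strain placed its cellodextrin (cld) genes. The other named features were, per sugar, the 15 highest rises and 10 largest falls that went the same way on both arrays. For the difference between sugars they were the 8 largest each way. Where under 5 features passed, the 10 with the smallest p were taken. The place of the cld genes could not be checked here, since 0 locus tags matched the reference table. Whether that knowledge drew on these same arrays is not known. Results in the window are therefore no independent evidence about the cld genes. Because tags carry no names, the text prints only the window, 2 further regions or tags that rose and 2 that fell, and treats the rest as counts. Of 23 gene lists fixed before the data were examined, the window was the 1 list with members. The other 22 needed gene names or products and could not be tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Runs of neighbouring tags (at least 2 tags changed by at least 1 on the log2 scale on both arrays in 1 direction) were tested against 10000 shuffles of the tag order.

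The alternatives tried, fixed before the data were examined, covered the background correction, the normalization, the source of the ratios, scaling between arrays, the filter on dim probes, saturated spots, the median of probes, a dye term, the arrays in the fit, the variance model, the threshold and each array left out. The labels describe a regularised t-test (Cyber-T) with p under 0.001 and a ratio over 3 or under 0.33. It was run on the same values with a window of 101 genes and a confidence of 10 and is called the methods' t-test. Alternatives chosen after the data were seen were the cellobiose dyes exchanged, locus tags alone, the removal of a trend along the tags, a smaller size of change for runs, and the tRNA and plasmid features as sets. Spike-in features were left out of the tests. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled tables and figures.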

Results

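The 4 arrays compared cells of B. breve UCC2003 grown on cellobiose or on cellodextrins with cells grown on glucose, with 2 arrays for each sugar. The study asked which genes the strain expresses differently when these plant-derived sugars replace glucose. Median spot signals ranged from 80.4 to 1678 over the 8 channels, and 85.9% to 99.2% of spots were well above background. The 10th percentile of signal was 1.16 to 6.43 times the negative controls in 7 channels and 18.5 times in the glucose (Cy5) channel of cellodextrins replicate 2. Log2 ratios over glucose, turned by the dyes named in the labels, correlated across features at r = 0.40 between the 2 cellobiose arrays and r = 0.50 between the 2 cellodextrins arrays. Features are not independent replicates, and these 6 pairwise correlations describe the arrays alone. The direction of each ratio rests on the dyes given in the labels. Arrays with the same dye orientation correlated at -0.03 (replicate 1 of each sugar) and -0.27 (replicate 2 of each sugar) between the sugars, and arrays with opposite orientation at -0.37 (cellobiose replicate 1 with cellodextrins replicate 2) and -0.26 (cellobiose replicate 2 with cellodextrins replicate 1). All signs of the cellobiose ratios below would turn if the dyes of both cellobiose arrays had been named the other way round.

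On cellodextrins, 58 features rose and 23 fell against glucose (limma, adjusted p under 0.05, n = 2 arrays). The features with the highest rise lay in the window of 7 tags fixed beforehand, the presumed and unchecked place of the cellodextrin genes. In it 5 neighbouring tags rose, Bbr_0106 to Bbr_0110. Their mean log2 ratio was 4.34, about 20.2-fold, with 5.91 on replicate 1 and 2.77 on replicate 2. The highest single value was at Bbr_0107, at 4.94 ± 0.74 (SE, limma adjusted p = 0.0175), with 6.77 and 3.11 on the 2 arrays. Bbr_0106 reached 4.59 ± 0.53 (SE, limma adjusted p = 0.0079). The lowest of the 5 was Bbr_0110 at 2.69 ± 0.49 (SE, limma adjusted p = 0.0314), and its 3 probes ranged from 2.19 to 3.57. The SD of these 5 tags was 1.67 to 2.66 between the cellodextrins arrays and 0.175 to 1.33 between the cellobiose arrays. The SEs pool the spread of all 4 arrays and so understate the spread of the cellodextrins pair. None of the 5 tags passed with the arrays scaled to equal spread. On replicate 2, all spots of Bbr_0106 and a share of 0.833 of those of Bbr_0107 were saturated, so both ratios there may understate the change and their order is not settled. The first tags of the window, Bbr_0104 and Bbr_0105, had log2 ratios of -0.55 and -0.56 and did not pass.

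Of the 58 rises on cellodextrins, 31 stood in blocks of neighbouring tags, the 5 of the window among them, and 27 did not. All 10 tags from Bbr_0846 to Bbr_0855 rose, with a mean log2 ratio of 2.30 (4.94-fold), 2.64 on replicate 1 and 1.97 on replicate 2, and single tags between 1.11 and 3.99. All 5 tags from Bbr_1832 to Bbr_1836 rose, with a mean of 2.64 (6.24-fold), 3.45 and 1.84 on the 2 arrays, and single tags between 2.26 and 2.80. Another 5 blocks of 2 or 3 tags rose by means of 1.36 to 1.51. Of the 57 tags changed by at least 1 on both arrays (40 up, 17 down), 33 stood in 9 blocks, 1 of which fell (Bbr_0182 and Bbr_0183), against at most 12 tags in 10000 shuffles of the tag order (p = 1e-04, the smallest these permutations can give). Fitted ratios of neighbouring tags correlated at r = 0.58.

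Among the falls on cellodextrins, Bbr_1594 had the lowest log2 ratio, -3.26 ± 0.41 (SE, limma adjusted p = 0.0101), with -3.78 and -2.74 on the 2 arrays. Bbr_0182 stood at -2.83 ± 0.22 (SE, limma adjusted p = 0.00226), with -2.99 and -2.68, and its neighbour also fell, giving a mean of -2.49 for this pair of tags. Of the 23 falls, 19 lay within the outer 25% of the tag numbers at either end, where ratios on replicate 2 were low as a whole. The median log2 ratio on that array was -0.60 in the first 10% of the tags, 0.35 just before the middle of the order and -0.46 in the last 10%, against -0.04, 0.05 and 0.01 on replicate 1. With this trend removed, 57 features were called (43 up, 14 down), 11 of the 23 falls and 38 of the 58 rises among them.

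The count on cellodextrins depended on the settings. It was 0 with the arrays scaled to equal spread, 28 with the log ratios of the scanner software, 45 without background correction, 48 with the median of probes, 133 with the strict filter on dim probes and 357 with a dye term. It was 15 with the 2 cellodextrins arrays alone or without either cellobiose replicate, 520 without cellodextrins replicate 1 and 200 without cellodextrins replicate 2. The balance moved from 58 up and 23 down to 48 up and 31 down with normexp at offset 0, 174 up and 183 down with a dye term, and 229 up and 291 down without cellodextrins replicate 1. Of the 81, 28 also had a ratio over 3 or under 0.33 (22 up, 6 down), and the methods' t-test called 26, all of them also called by limma.

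**Figure D1:**
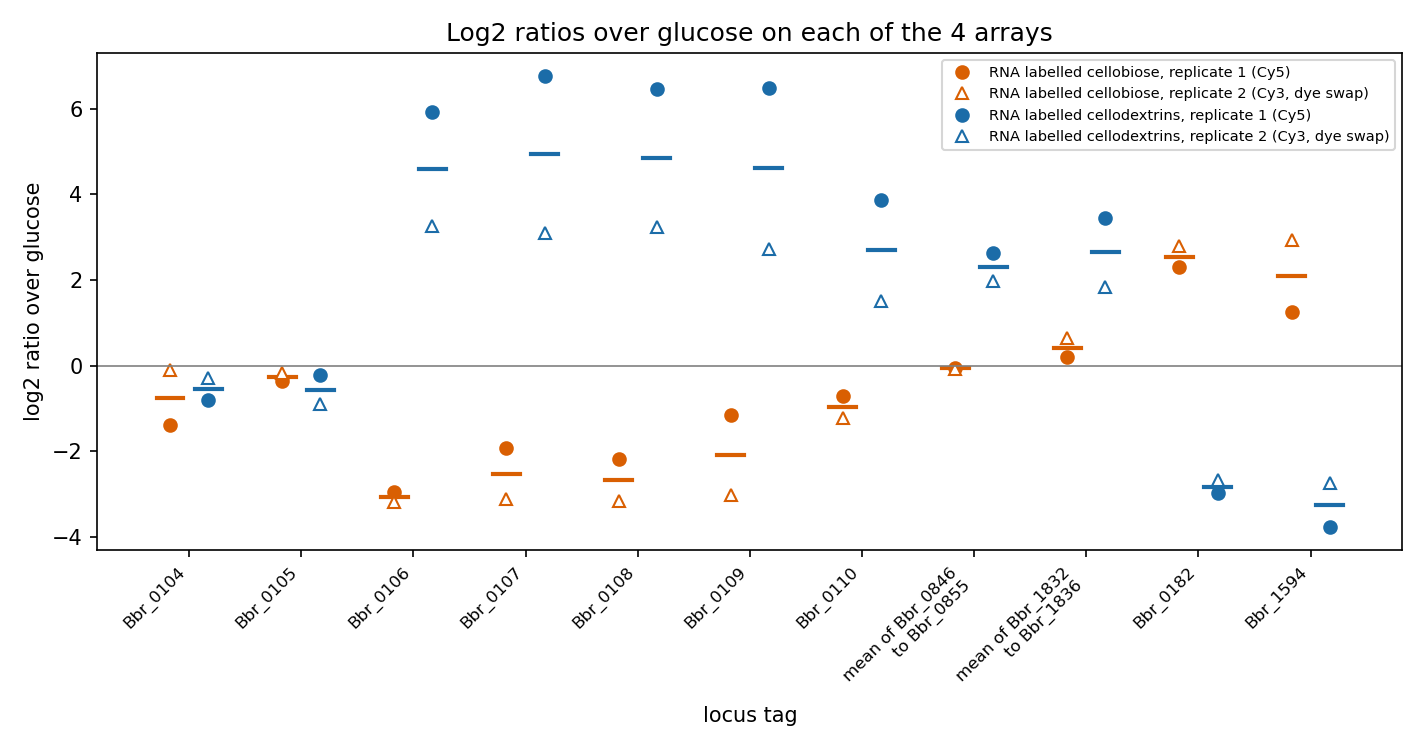
Log2 ratios over glucose (vertical axis) of the 7 tags of the window fixed beforehand, the means of 2 further blocks and 2 single tags (horizontal axis). Filled circles are replicate 1, open triangles the dye-swapped replicate 2, and bars the mean of both, with cellodextrins in blue and cellobiose in orange. Bbr_0107 stood at 6.77 and 3.11 on the cellodextrins arrays, and Bbr_0182 at 2.31 and 2.78 on the cellobiose arrays as labelled.

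On cellobiose, 1 feature, Bbr_0182, passed against glucose in the fit that pooled the spread of all 4 arrays. With each pair's own arrays alone, limma called 26 features on cellobiose and 15 on cellodextrins. The pooled counts of 1 and 81 therefore do not rank the 2 responses. Bbr_0182 rose, as labelled, with a log2 ratio of 2.55 ± 0.22 (SE, limma adjusted p = 0.00963) and 2.31 and 2.78 on the 2 arrays. In the pooled fit no feature was called as lower by limma, and 5.42% of the 1865 features had an unadjusted p under 0.05, against 5% by chance. That number rose to 202 features with median centring and 247 with the cellobiose arrays alone. The 4 tags Bbr_0106 to Bbr_0109 had negative ratios on both arrays, with a mean log2 ratio of -2.59, -2.05 on replicate 1 and -3.13 on replicate 2. None of these passed with limma in the pooled fit over all features tested: the smallest limma adjusted p was 0.256, at Bbr_0106 (-3.07 ± 0.53, SE). Bbr_1594 had a log2 ratio of 2.09 ± 0.41 (SE, limma adjusted p = 0.441). Only 8 tags changed by at least 1 on both arrays, and 6 of them stood in 2 blocks, against at most 2 tags in 10000 shuffles (p = 1e-04, the smallest these permutations can give).

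The cellobiose count was 38 with a dye term (23 up, 15 down), 26 with the 2 cellobiose arrays alone or without either cellodextrins replicate, 4 with the log ratios of the scanner software, and 0 without either cellobiose replicate, with scaled arrays or with the trend along the tags removed. Bbr_0182 itself had a log2 ratio between 1.92 and 3.78 on cellobiose in the 21 other settings and passed in 16 of them. With median centring in place of loess, the split changed from 1 up and 0 down to 0 up and 1 down, the fall being Bbr_0106 at -3.72. The methods' t-test called Bbr_0182, Bbr_0183 and Bbr_1594 up and the 4 tags Bbr_0106 to Bbr_0109 down at its threshold. After Benjamini-Hochberg adjustment 4 of these 7 were left, Bbr_0106 to Bbr_0108 and Bbr_0182. On cellodextrins that test gave 25 after adjustment.

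**Figure D2:**
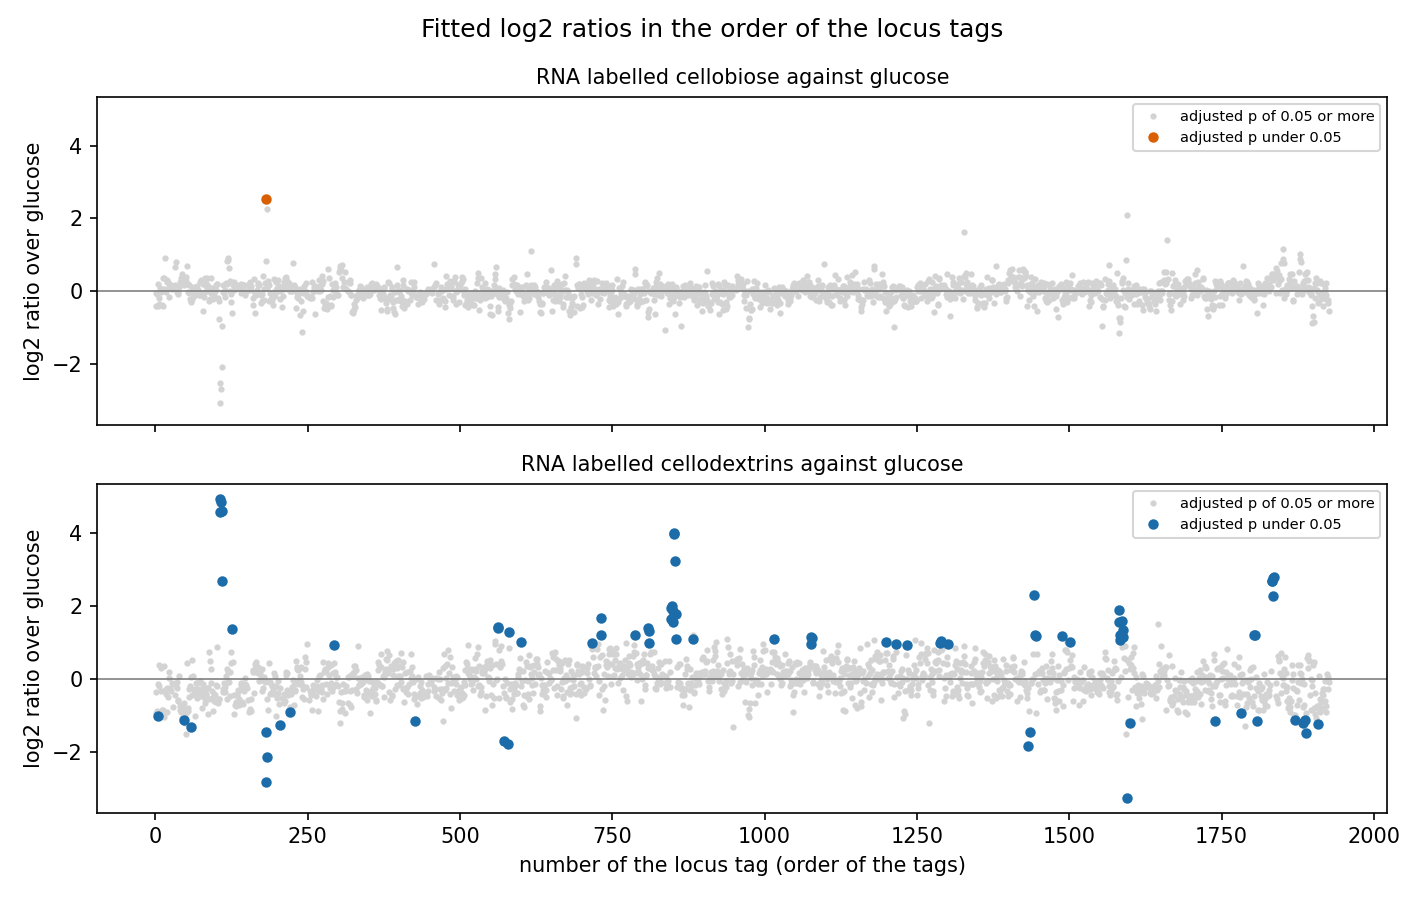
Fitted log2 ratios over glucose (vertical axes) of each locus tag in the order of the tag numbers (horizontal axis), for cellobiose (top) and cellodextrins (bottom). Coloured points passed an adjusted p under 0.05 and grey points did not, and the cellodextrins panel shows the blocks that rose as steep columns of points.

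The window of 7 tags was the only gene list with members on the array. Adjusted over the list alone, 5 tags passed as higher on cellodextrins, 3 as lower on cellobiose and 5 as higher on cellodextrins than on cellobiose, where adjustment over all features tested gave 5, 0 and 4. The median log2 ratio of the window was 4.59 on cellodextrins and -2.09 on cellobiose. Camera with a preset correlation gave adjusted p = 0.000983 for cellodextrins (up), 1.05e-08 for cellobiose (down) and 4.68e-06 for the difference. With an estimated correlation of 0.518, adjusted p = 0.396 for each of the 3 comparisons, and with fry adjusted p = 0.366 for each. Taken as 1 averaged value, the window had a log2 ratio of 2.94 ± 0.47 on cellodextrins (SE, limma adjusted p = 0.0235) and -1.76 ± 0.47 on cellobiose (SE, limma adjusted p = 0.665).

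Between the sugars, 18 features differed in their response, 15 higher on cellodextrins than on cellobiose and 3 lower. All 18 were also called on cellodextrins against glucose, and 16 had opposite signs against glucose on the 2 sugars, as labelled. Among them were 4 neighbouring tags of the window, and Bbr_0106 differed by 7.66 ± 0.75 on the log2 scale (SE, limma adjusted p = 0.00473), with all its spots saturated on cellodextrins replicate 2. Of the block Bbr_0846 to Bbr_0855, 5 tags differed. The mean of that block was 2.30 on cellodextrins and -0.07 on cellobiose. Bbr_0182 and Bbr_1594 were lower on cellodextrins than on cellobiose by -5.38 ± 0.31 (SE, limma adjusted p = 0.000545) and -5.35 ± 0.58 (SE, limma adjusted p = 0.00794). No tag of the block Bbr_1832 to Bbr_1836 passed this test, although its mean was 2.64 on cellodextrins and 0.42 on cellobiose. The sugars were given at 0.85% and 1%, and each was compared with its own glucose channel. With the cellobiose dyes exchanged, 0 features were called between the sugars by limma, and 243 had an unadjusted p under 0.05. The differences then were 1.52 for Bbr_0106, -0.29 for Bbr_0182, -1.17 for Bbr_1594 and 2.24 for the mean of Bbr_0846 to Bbr_0855 (2.37 as labelled). The count was 232 with a dye term (113 up, 119 down), 87 with median centring, 30 with normexp at offset 0 or the strict filter, 10 with the median of probes, 5 with the trend along the tags removed and 0 with scaled arrays. It was 3 and 1 without cellobiose replicates 1 and 2, all of them down. It was 525 (234 up, 291 down) and 86 (51 up, 35 down) without cellodextrins replicates 1 and 2.

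Across the 1865 features, the 2 fitted sugar responses correlated at r = -0.32 (Spearman's rho = -0.22), with a covariance of -0.06. Unchanged groups simulated in 100 draws gave r = 0.50 and a covariance of 0.04 where the glucose RNA was shared, and r between -0.09 and 0.10 where it was not. Simulated errors were independent between features, whereas fitted ratios of neighbouring tags correlated at r = 0.52 on cellobiose and 0.58 on cellodextrins. The simulated range is therefore too narrow to test the observed r. No feature was called in the same direction on both sugars. The 1 feature called on both, Bbr_0182, was higher on cellobiose and lower on cellodextrins, against 0.0123 features for independent lists. Both tests used the same spread estimate of each feature, so the lists were not independent and this expectation tests nothing. With the cellobiose dyes exchanged, r was 0.32.

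**Figure D3:**
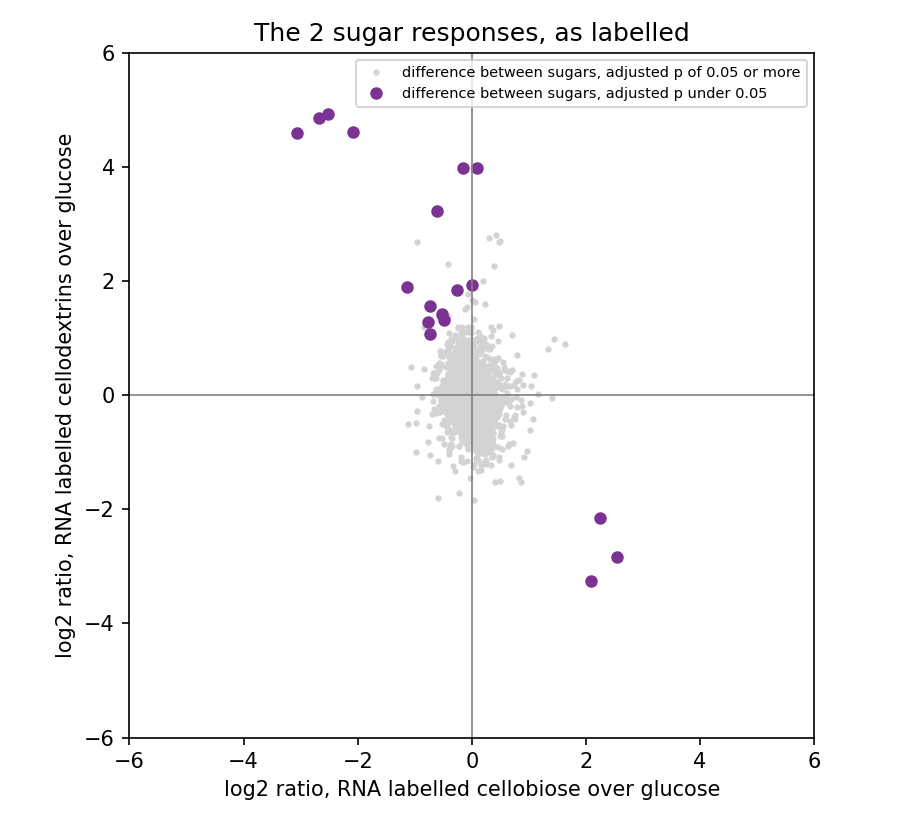
Fitted log2 ratio over glucose on cellodextrins (vertical axis) against that on cellobiose (horizontal axis), as labelled, with 1 point per feature. Purple points are the 18 features that differed between the sugars at an adjusted p under 0.05, of which 16 lie in the quadrants of opposite sign.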

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

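The tests of explanations in this part were chosen only after the results were seen, and the difference between the sugars itself was planned. A test of the difference between the sugar responses picked out 18 features. It also picked out the mean of the window of 7 tags (4.70 on the log2 scale, cellodextrins minus cellobiose), Bbr_0182 (-5.38), Bbr_1594 (-5.35) and 5 tags of the block Bbr_0846 to Bbr_0855. With the cellobiose dyes exchanged, these differences would be 1.18 for the window, -0.29 for Bbr_0182 and -1.17 for Bbr_1594, and 0 features were called by limma (243 at an unadjusted p under 0.05).

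The first pattern is that 16 of these 18 features had opposite signs on the 2 sugars, which a test for a large difference favours. Signs were opposite for 59.3% of the features called on cellodextrins and 60.4% of the others, most with small ratios on cellobiose. A choice without the difference took features called on cellodextrins with an unadjusted limma p under 0.05 on cellobiose. It held 18 features, 16 opposite in sign and 2 the same, so the pattern was also seen without selection by the difference. Both choices used the same arrays and shared Bbr_0106 to Bbr_0109, Bbr_0182, Bbr_0183 and Bbr_1594. Because neighbouring tags go together, these counts are not a test of the pattern. All 16 opposed features of the difference test kept their sign on both arrays of both pairs. All 58 rises and 23 falls called on cellodextrins also kept theirs on both cellodextrins arrays. The kept signs therefore say nothing about a gene-specific dye bias, which the swap cancels in the mean of a pair by design. If the dyes of both cellobiose arrays were exchanged in the labels, the glucose signal ranks of both comparisons should lie closer together with the dyes turned, and they did so for 8 of 16 features (exact sign test, two-sided p = 1). As labelled, the signed gap of the ranks was above 0 for 11 of 16 (exact sign test, two-sided p = 0.21). The tags with the largest cellobiose ratios, Bbr_0106 to Bbr_0109, Bbr_0182, Bbr_0183 and Bbr_1594, all lay closer with the dyes exchanged. For Bbr_0182 the gap was 16.7 percentile points as labelled and 0.7 exchanged, and for Bbr_0108 it was 29.9 and -23.4. Bbr_0849 also lay closer with the dyes exchanged (13.6 as labelled, 2.8 exchanged), and its block had a mean log2 ratio of -0.07 on cellobiose. The 8 features closer as labelled had smaller cellobiose ratios than the tags with the largest. This split was not tested, and neighbouring tags are not independent. An exchange of dye names and an opposite response of the cultures cannot be told apart by these ranks. Both the signs on cellobiose and the sizes of the differences between the sugars stay open.

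The second pattern is that 14 of the 58 rises on cellodextrins were larger on replicate 1 than on replicate 2 by over 1 on the log2 scale, with medians of 3.75 and 2.10. Saturated spots do not account for 12 of the 14, which held none on either array. At most 0.31% of spots were saturated in any channel. A sign test against an even split (exact, two-sided p = 0.0129) therefore adds nothing to that count. A floor common to all Cy5 spots of replicate 2 would also lift probes without a target, but that channel's negative controls had a median signal of 51.1 and a highest of 200, against a 10th percentile of 944 for the other spots (18.5 times that median). A higher rank of glucose signal on replicate 2 was seen for 13 of the 14 and for 11 of the other 44 rises, but the 14 were picked by their ratios, so these ranks decide nothing. The negative controls cannot show a floor common to probes with a chromosomal target alone. Such a floor, a floor that differs between genes and a higher level of these genes in that glucose culture stay open.

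The third pattern is the trend along the tag order on cellodextrins replicate 2, whose log2 ratios correlated with the cosine of the tag number at r = -0.45 (10000 permutations of blocks of 20 tags, adjusted p = 2e-04 over the 4 arrays). A weaker trend on cellobiose replicate 2 (r = 0.16, adjusted p = 2e-04) was not seen with median centring (r = 0.04, permutation p = 0.346), and r was 0.04 on cellobiose replicate 1 and -0.01 on cellodextrins replicate 1 (adjusted p = 0.455 and 0.892). Loess was not the whole source on cellodextrins replicate 2, since r was -0.22 there with median centring (p = 1e-04, the smallest these permutations can give). The ratio's slope was steeper by -0.20 (95% block bootstrap interval -0.32 to -0.09) in the 613 tags with the dimmest glucose signal on replicate 1 than in the 613 brightest, while slopes from the dimmest to the brightest tags were 0.33, 0.32 and 0.34 in the glucose channel (difference -0.011, interval -0.18 to 0.13), 0.01, 0.06 and 0.21 in the cellodextrins channel, -0.03, 0.02 and 0.29 in the glucose channel of replicate 1, and 0.27, 0.26 and 0.23 (glucose) and 0.15, 0.19 and 0.21 (cellobiose) on cellobiose replicate 1. Chromosomal DNA labelled with that glucose RNA, if tag numbers start near the replication origin, is 1 explanation. A gene copy number that differed between the cultures is another. They cannot be told apart, because even slopes were not peculiar to that channel. Channels with flat slopes among dim tags had 10th percentiles nearer the negative controls (3.31 and 1.16 times, against 18.5), which may flatten them. The cellobiose channel of cellobiose replicate 1 stood at 3.21 times without such flat slopes, so a low 10th percentile does not always go with them.

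The 7 spike-in features, which entered no comparison, had up to 33.3% of their spots well above background, against up to 8.86% of negative control spots. Their share was above that of the negative controls in 7 of 8 channels, and the labels name no spike-in RNA.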

How the results depend on the processing

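Exchanging the cellobiose dyes, restricting to locus tags and removing the trend along the tags were chosen only after the results were seen, and the other settings were planned. The correlation of the sugar responses stayed below 0 in every setting where it was computed with the cellobiose dyes as labelled (-0.17 to -0.49). It was -0.49 with median centring, and 0.32 with the cellobiose dyes exchanged, a turn that follows from the construction. Calls on cellobiose numbered 3 with normexp at offset 0, 4 with the scanner software's log ratio and with the series value table, 0 with scaled arrays, 2 with the strict filter, 38 with a dye term, 26 with the pair's own arrays, 7 with the methods' t-test and 0 with the trend along the tags removed, against 1. Calls on cellodextrins numbered 45 without background correction, 28 with the scanner software's log ratio and with the series value table, 0 with scaled arrays, 133 with the strict filter, 48 with the median of probes, 357 with a dye term, 15 with the pair's own arrays, 26 with the methods' t-test and 28 with the added ratio limit, against 81. Calls between the sugars numbered 30 with normexp at offset 0, 87 with median centring, 0 with scaled arrays, 30 with the strict filter, 10 with the median of probes, 232 with a dye term, 5 with the trend along the tags removed and 0 with the cellobiose dyes exchanged, against 18. Scaled arrays gave 230, 230 and 302 features at an unadjusted p under 0.05. The rise with a dye term went with infinite estimated prior degrees of freedom: at the prior degrees of freedom of the fit without that term, a dye term gave 2, 36 and 16 calls. The cause of the other moves was not tested. Leaving out 1 array at a time gave 0 to 26 calls on cellobiose, 15 to 520 on cellodextrins, 1 to 525 between the sugars and a correlation of -0.38 to -0.17, where the array left alone was assumed to vary like the other pair. Bbr_0183, the neighbour of Bbr_0182, turned to 0.11 between the sugars with the cellobiose dyes exchanged. The 5 tags Bbr_0106 to Bbr_0110 had a mean of 3.45 to 4.92 on cellodextrins over the 7 scalings. Replicate numbers of the 2 sugars name dye orientations, so a term that pairs the arrays by replicate number is the dye term above. A slide or scan block was not run, since each array was its own slide and day. Median signals were 2.05 (Cy3) and 2.83 (Cy5) times the negative controls on cellobiose replicate 2, and 2.81 (Cy3) and 3.70 (Cy5) times on cellodextrins replicate 1, which limits what dim spots of both arrays can show.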

Other observations

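The tests in this part were chosen only after the results were seen. The array carried 20 tRNA features. On cellobiose, as labelled, all 20 had a log2 ratio above 0, with a median of 0.52, and on cellodextrins 16 of 20 had a ratio below 0, with a median of -0.41. No single tRNA feature passed over all features tested on either sugar or between the sugars. The feature with the smallest p on cellobiose was tRNA-Ala, at 1.01 ± 0.24 (SE, limma adjusted p = 0.618), and on cellodextrins it was tRNA-Cys, at -0.86 ± 0.21 (SE, limma adjusted p = 0.0594). As a set, camera with a preset correlation gave adjusted p = 2.04e-09 on cellobiose, 0.0235 on cellodextrins and 4.64e-06 between the sugars. With an estimated correlation of 0.416, these became adjusted p = 0.396, 0.626 and 0.396, and fry gave adjusted p = 0.371, 0.406 and 0.366. The medians kept their sign under the 6 other scalings, with median centring giving 0.25 on cellobiose and -0.21 on cellodextrins.

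The 5 plasmid and insertion sequence features that passed the filter had median log2 ratios of -0.07 on cellobiose and 0.15 on cellodextrins, and none was called. Their set gave camera adjusted p = 0.352 and 0.331 on the 2 sugars with a preset correlation. The 16S rRNA feature had log2 ratios of -0.26 on cellobiose and 0.45 on cellodextrins, with limma adjusted p = 0.999 and 0.472, and the 2 cellodextrins arrays differed in sign (-0.39 and 1.29).

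The part of the ratios that went with the dye (the mean of an array and its swapped partner before turning) correlated between the 2 pairs at r = 0.31 across features, against at most 0.10 in 10000 permutations (p = 1e-04, the smallest these permutations can give). Neighbouring tags are not independent, so this p may be too small. With the trend along the tags removed, 30 tags on cellodextrins stood in 10 blocks of neighbours, against at most 12 in 10000 shuffles, and 25 of them were among the 33 tags that stood in blocks with the trend kept. At a size of change of 0.58 on the log2 scale, 99 tags on cellodextrins and 21 on cellobiose stood in such blocks, against at most 39 and 6 in 1000 shuffles.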
